A study of Mus musculus with 8 samples.

How the data were processed

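Gene expression was measured in CD8+ T cells of C57BL/6 mice, the T cells that differentiate into cytotoxic T lymphocytes. Each of the 8 samples was hybridised to 1 array of the Illumina MouseRef-8 design. The labels placed 4 samples in a wild type group and 4 in a group that lacks ASC, the adaptor protein encoded by Pycard. The labels do not say whether the replicates came from separate animals, so the p-values measure the spread between these samples, which may be partly technical. Stimulation, time points, slides and array positions are not given in the sources used here, so no batch was tested.

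Per the labels' protocols, RNA was extracted on a Qiagen column, treated with DNase and amplified into biotinylated cRNA. GenomeStudio was used per the submitters' processing notes, with no version given. Per the file headers, the deposited intensity of each probe on each array was not normalized, and the lowest values lay above 100, so no background had been subtracted. Per the file headers, each deposited detection p-value belongs to 1 probe on 1 array. The deposited value table of the authors holds log2 values, as the comparison with the probe signals showed: it equals quantile-normalized log2 signals without background correction, centred on each probe's median over the 8 arrays, within 0.00059. Its column medians ran from -0.00045 to 0.00053, and its values are differences with no absolute level. The authors' scaling and centring were found from the values, since no header states them, and the direction follows the signal.

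The intensities of all 25697 probes were corrected with limma's nec function, whose background mean and SD were inferred from the detection p-values, with an offset of 16. They were then quantile-normalized and put on the log2 scale. Probes with a detection p-value under 0.05 on at least 4 of the 8 arrays were tested, which left 11270 probes or 43.9%. Differences between knockout and wild type were fitted with limma's lmFit and eBayes, and p-values were adjusted by the Benjamini-Hochberg method over the tested probes, with a threshold of 0.05. A gene counted once, whichever of its probes passed. Of all probes, 23978 had 1 gene symbol in the platform annotation, 0 had several and 1719 had none. Symbols of 23962 probes were matched through Entrez identifiers to a gene table of assembly GRCm38.p6. The tested probes covered 7759 named genes, of which 2046 had 2 or more tested probes, and 655 tested probes had no name.

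Where a group did not detect a probe on any array, the size of its difference is given as a bound. It is the mean of the other group over the dim group's mean of, per array, the higher of the lowest signal among detected probes and the probe's own signal. The array count limits the precision of all values. The median standard error of a log2 difference was 0.109.

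Gene lists, 28 in number, were fixed before the data were examined, as was the rule for named genes. So were the tests and the alternatives, apart from those named below as chosen later. Each list used the brightest tested probe per gene, and a member called only at another probe is named where the list is given. limma's camera compared a list with the other genes at a preset correlation of 0.01, and again with the correlation estimated for each list. limma's fry tested whether a list's own genes moved, on balance, in 1 direction. List p-values were adjusted over the 28 lists, and members also over the list alone. The named genes were Pycard, the 12 largest called differences in each direction, up to 4 called genes per list, and 16 genes of cytotoxic T cells and the inflammasome whatever their result, of which 1 is not reported here. Genes within 20 Mb of Pycard were compared with all other placed genes by a two-sided Fisher's exact test, leaving out Pycard itself. The gene table served only for names, neighbours and this window, and it placed 99.96% of the tested genes.

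The alternatives changed the background model, the normalization, the detection filter, the source of the values, the array weights, the variance model, the probes per gene, the window, the set test and the replicates used. They also set the replicate number as a block. The code was tested on simulated arrays built from the means and spreads of the 11270 tested probes, with 200 probes changed. At a log2 difference of 1 the fit called 92% of the changed probes, at 0.5 it called 51%, and 0 had the wrong sign. Among its calls, 5.92% were unchanged probes. In 20 simulated sets without any change it called 0 probes and 0 lists, though simulated genes were independent of each other and real genes were not. A simulated odds ratio of 4.08 around Pycard was found as 4.0. Computations used R 4.3.3 and limma 3.58.1.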

Results

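Transcript levels were compared in CD8+ T cells of mice with and without ASC, an adaptor best known for assembling inflammasomes, the complexes that activate caspase-1. The title of the study places ASC in T-bet-dependent differentiation of cytotoxic T cells, so the comparison asks which genes, and which effector genes above all, differ in its absence. There were 4 wild type and 4 ASC knockout samples, with 1 single-colour bead array each. The median probe signal lay between 127.9 and 133.8 on all 8 arrays. The mean signal was 553.7 ± 27.5 in wild type and 512.4 ± 9.56 in the knockout (SD, n = 4 each, exact permutation p = 0.0571). Between 42.8% and 45.4% of the 25697 probes were detected on an array. The mean number of detected probes was 11228 ± 230 (SD, n = 4) in wild type and 11608 ± 65.5 (SD, n = 4) in the knockout, a difference with an exact permutation p of 0.0286, the smallest this design can give. Within a group the arrays correlated at 0.991 to 0.9944 across probes, and between groups at 0.9877 to 0.9902. Among principal components of the tested probes, component 1, with 28.9% of variance, separated wild type from knockout. Component 2, with 15.7%, set wild type replicates 1 and 2 (11.4 and 6.38) apart from 3 and 4 (-12.1 and -10.3). Knockout replicates ran from -7.96 to 7.53 on component 2. The cause of this spread within groups was not tested.

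Pycard (probe ILMN_2936476), the gene for ASC, was detected on 4 of 4 wild type arrays and on 0 of 4 knockout arrays. Its mean signal was 500.1 ± 19.0 (SD, n = 4) in wild type and 121.5 ± 2.57 (SD, n = 4) in the knockout. Expression was at least 12.7-fold lower in the knockout (limma adjusted p = 1.15e-09). The bound depended on the background model, and was 5.43-fold with normexp at an offset of 50 and 3.58-fold without background correction.

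Beyond Pycard, the knockout cells had higher transcripts of the endosomal GTPase Rab4a, the cytokine GM-CSF (Csf2), the peptide transporter Slc15a2 and the glucocorticoid-induced leucine zipper gene Tsc22d3. They had lower transcripts of the translation cofactor Paip1, the transcription factor Msc and the surface receptor Cd7. In log2 units with SE, at n = 4 per group, Rab4a rose by 2.12 ± 0.143, Csf2 by 1.89 ± 0.299, Slc15a2 by 1.85 ± 0.14 and Tsc22d3 by 1.48 ± 0.257. Slc15a2 was detected on 1 of 4 wild type and 4 of 4 knockout arrays, at mean signals of 132.8 ± 7.93 and 200.9 ± 11.2 (SD, n = 4 each), so the size of its difference is uncertain. Paip1 fell by 1.76 ± 0.0844, Msc by 1.15 ± 0.139 and Cd7 by 0.95 ± 0.148. In all, 88 genes passed limma's adjusted p of 0.05, with 48 higher and 40 lower in the knockout. Of these, 21 differed by at least 1 on the log2 scale. The groups did not overlap in any of the 88 genes, and in 8.12% of all tested probes, where chance gives 2.86%.

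Several other transcription factor genes were higher. Klf4, a zinc finger factor, rose by 1.19 ± 0.106, Foxp3, the factor that defines regulatory T cells, by 1.09 ± 0.138, and Epas1, a hypoxia-inducible factor, by 1.08 ± 0.208. The immediate early genes Fosb and Fos rose by 1.14 ± 0.203 and 0.65 ± 0.122, and the phosphatase gene Dusp1 by 1.03 ± 0.151. Cxcr4, a chemokine receptor for homing to bone marrow, rose by 0.85 ± 0.156. Tpbg was detected on 0 of 4 wild type and 4 of 4 knockout arrays, at least 1.78-fold higher in the knockout (limma adjusted p = 0.0015). Tmem254a fell by 1.43 ± 0.113 and Entpd4 by 0.97 ± 0.0838, though both have near-identical gene copies that a probe may not separate. Mgarp and Tulp4 fell by 0.89 ± 0.155 and 0.87 ± 0.134.

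Leaving out 1 array at a time lowered the counts to between 15 and 38 genes higher and between 15 and 32 lower. The counts moved by over 1.5 times in at least 1 direction without wild type replicate 1 (27 higher, 17 lower), 2 (15 and 15) or 3 (29 and 17), or without knockout replicate 1 (36 and 23), 2 (25 and 28), 3 (27 and 19) or 4 (26 and 19). Median scaling over all probes gave 32 genes higher and 55 lower, so that 36.8% of calls were higher against 54.5% with quantile normalization. It left the tested probes at a median log2 difference of -0.0827. Median scaling over detected probes, chosen after seeing the data, gave 58 higher and 42 lower, or 58% higher. Calls of Tsc22d3, Fosb, Fos, Epas1 and Gzmb each held in 1 of the 8 fits without an array, those of Cxcr4, Irgm2, Gbp3 and Mgarp in 2, Tulp4 in 3, Cd7 in 4, Bcl3 in 5 and Csf2 in 6. Without background correction, some log2 differences of named genes were over 1.5 times smaller. Among these, the higher called genes were Gdpd3 (3.30), Rab4a (1.11), Slc15a2 (0.64), Klf4 (0.49), Epas1 (0.48), Foxp3 (0.48) and Pgk1 (0.36). The lower called genes were Apobr (-1.03), Paip1 (-0.65), Gzmb (-0.40) and Mgarp (-0.29). Those not called were Gzma (0.19), Il1b (0.09) and Il18 (-0.02). The bounds for Tpbg and Itgad were then 1.18-fold and 1.34-fold.

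**Figure D1:**
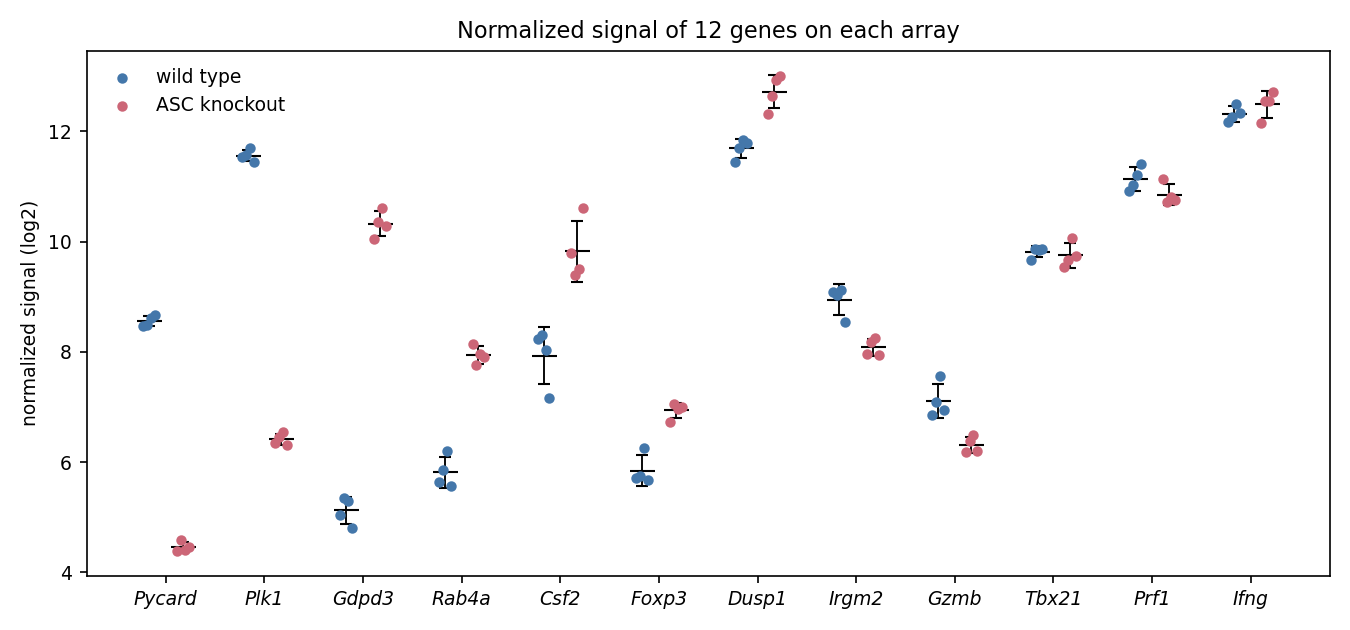
Normalized log2 signal of 12 genes on each array, with wild type in blue and ASC knockout in red; each point is 1 array, and the black line and bar give the mean and SD (n = 4). Plk1 differs by -5.15 log2 units and Pycard is undetected in the knockout, whereas the points of Tbx21, Prf1 and Ifng overlap.

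The 2 largest changes lay close to Pycard on chromosome 7. Plk1 (probe ILMN_1255053), which encodes a mitotic kinase, fell by 5.15 ± 0.0881 on the log2 scale, from a mean signal of 3298 ± 228 to 188.4 ± 6.2 (SD, n = 4 each). Gdpd3 (probe ILMN_2893879), a phosphodiesterase gene detected on 3 of 4 wild type arrays, rose by 5.20 ± 0.147, from a mean signal of 142.4 ± 5.62 to 1340 ± 205 (SD, n = 4 each). Rgs10, a regulator of G protein signalling, fell by 2.56 ± 0.268. Apobr, a lipoprotein receptor gene, fell by 1.77 ± 0.123. The integrin gene Itgad was detected on 0 of 4 knockout arrays at probe ILMN_1237406 and was at least 2.51-fold lower there (limma adjusted p = 1.78e-05). Its probe ILMN_3092056, also detected on 0 of 4 knockout arrays, was at least 1.98-fold lower. A dim Itgad probe, ILMN_3019915, was detected on 1 of 4 wild type and 3 of 4 knockout arrays and differed by 0.11 ± 0.132. Kdm8 and Wdr11 fell by 0.48 ± 0.0884 and 0.56 ± 0.105, and Bag3 and Plekha1 rose by 0.76 ± 0.112 and 0.54 ± 0.0849. These last 4 were named after their values were seen.

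Within 20 Mb of Pycard, 9 of 192 tested genes were called, or 4.69%, with 3 higher and 6 lower and Pycard itself left out. Elsewhere it was 78 of 7563 genes, or 1.03%. The odds ratio was 4.72, with a 95% interval of 2.05 to 9.62 (two-sided Fisher's exact p = 0.000281). On the rest of chromosome 7, 3 of 414 genes were called. Of the 21 genes that differed by at least 1 on the log2 scale, 6 lay in this window, Pycard included.

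**Figure D2:**
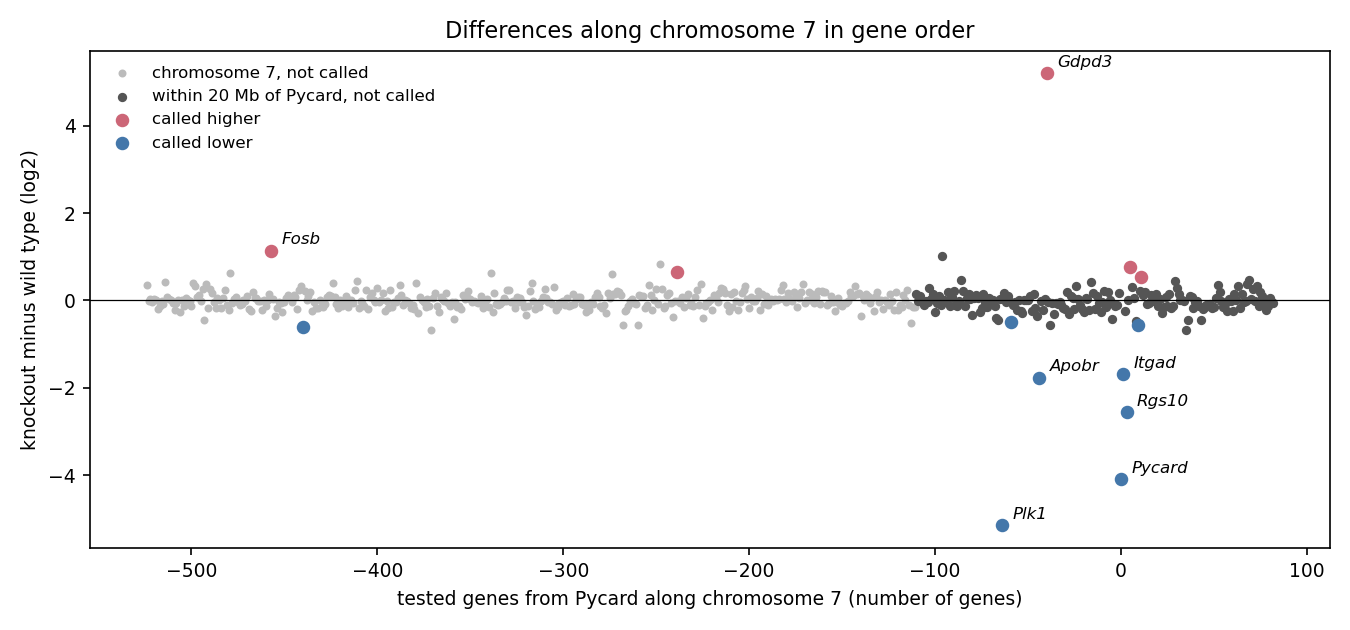
Knockout minus wild type differences (log2) of the tested genes of chromosome 7, placed by their order in number of genes from Pycard; red and blue points are genes called higher and lower, dark grey points other genes within 20 Mb of Pycard, light grey points the rest. Gdpd3 at 5.20 and Plk1 at -5.15 are the extremes, and 9 called genes besides Pycard lie in the window.

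Of the cytotoxic effector genes, Gzmb, which encodes granzyme B, fell by 0.80 ± 0.149 on the log2 scale (SE, n = 4 per group, limma adjusted p = 0.0439). Its probe was dim, at mean signals of 251 ± 23.8 in wild type and 183 ± 7.46 in the knockout (SD, n = 4 each). Without background correction the difference was -0.40, so its size is uncertain. The call held only in the fit without wild type replicate 3 when arrays were left out, and the difference then ranged from -0.88 to -0.64. No other measured member passed, out of 19. Perforin (Prf1) was at -0.28 ± 0.131, granzyme A (Gzma) at 0.32 ± 0.34, the maturation marker Klrg1 at 0.32 ± 0.179 and interferon gamma (Ifng) at 0.17 ± 0.127. Leaving out 1 array moved Gzma between 0.09 and 0.60, Klrg1 between 0.18 and 0.46 and Ifng between 0.10 and 0.29. The list as a whole did not pass limma's camera (adjusted p = 0.834), with a median of 0.03, and 1 member passed when adjusted over the list alone.

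Tbx21, the gene for T-bet, differed by -0.06 ± 0.118 (95% interval -0.32 to 0.20), and the related factor Eomes by 0.10 ± 0.133, which moved between 0.02 and 0.18 when 1 array was left out. Of 19 measured genes associated with T-bet, 0 passed over all genes and 0 when adjusted over the list alone, while 2 had an unadjusted limma p under 0.05. The list's median was -0.01 and its mean 0.05, of opposite sign, and camera's adjusted p was 0.585 in the direction of the mean. The interleukin 7 receptor gene Il7r was at 0.84 ± 0.237 (limma adjusted p = 0.152) and Cd44 at 0.14 ± 0.101, between 0.08 and 0.21 without 1 array. Prdm1 and Nlrp3 had probes that did not pass the detection filter, and Dock2 had no named probe among those used here.

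In the inflammasome and interleukin 1 family, Pycard was the only called gene of 11, also when adjusted over the list alone, with camera's adjusted p at 0.44. Casp1, the gene for caspase-1, differed by -0.01 ± 0.0977, Il18 by -0.05 ± 0.192 and Il1b, which 1 wild type and 3 knockout arrays detected, by 0.30 ± 0.221, between 0.08 and 0.48 without 1 array.

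Genes of the interferon gamma response and antigen presentation were lower in the knockout, with 18 of 20 measured members below 0 and a median of -0.17. Irgm2 and Gbp3, guanosine triphosphatases induced by interferon gamma, fell by 0.86 ± 0.14 and 0.66 ± 0.127, and Gbp3 has close paralogs. Irf1, a transcription factor gene, was called through 2 dimmer probes that fell by 0.84 and 0.69, while its brightest probe, at -0.46 ± 0.139, did not pass. Over all genes 3 members were called, 2 of them at their brightest probe, and 7 brightest probes passed when adjusted over the list alone, all lower. limma's camera gave an adjusted p of 1.88e-06 for the list, but adjusted p = 0.22 with an estimated correlation. The type I interferon list, with 17 of 22 members below 0, had 0 called genes over all genes and 0 when adjusted over the list alone. Its camera adjusted p was 0.0469, and adjusted p = 0.622 with an estimated correlation. That call was lost without wild type replicate 1 (adjusted p = 0.0929), 2 (0.0744) or 3 (0.247) or knockout replicate 1 (0.304).

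Markers of CD4 and regulatory T cells were higher, with 9 of 10 measured members above 0 and a median of 0.38. Foxp3 was the only called gene over all genes, and 6 passed when adjusted over the list alone, all higher: Foxp3, Gata3, Tnfrsf18, Ctla4, Il2ra and Tnfrsf4. A second Foxp3 probe differed by 1.01 without passing. limma's camera gave an adjusted p of 1.2e-05 for the list, and adjusted p = 0.0597 with an estimated correlation. The neutrophil genes S100a9 and S100a8 were at 1.08 ± 0.329 and 0.83 ± 0.32 and the haemoglobin gene Hba-a1, which has a near-identical copy, at 0.97 ± 0.3, none past limma's adjusted p.

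T cell activation genes were also higher, with 14 of 19 members above 0. Fos was called over all genes and 6 genes when adjusted over the list alone, among them Icos, Cd69 and Junb. The camera adjusted p was 0.0152, and adjusted p = 0.367 with an estimated correlation. Among NF-kB targets, 15 of 18 were above 0, but the 1 called gene, Bcl3, an atypical inhibitor of NF-kB, fell by 0.60 ± 0.0903. Adjusted over the list alone, 4 were higher and 1 lower, and camera gave an adjusted p of 0.0172, and adjusted p = 0.367 with an estimated correlation. Without knockout replicate 4 both lists lost the call, at adjusted p = 0.0993 for activation and 0.0571 for NF-kB. Of the heat shock and handling stress genes, which share Fos and Junb with activation, 3 of 15 were called, all higher, and 5 higher and 2 lower passed when adjusted over the list alone. Its camera adjusted p was 0.106.

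Cell cycle genes were lower by camera (adjusted p = 0.0172, and adjusted p = 0.367 with an estimated correlation), with 21 of 26 members below 0. Plk1 was the only called member over all genes, and Plk1 and Cdk1 passed when adjusted over the list alone. Without the genes near Pycard, Plk1 among them, the adjusted p was 0.112, and it was 0.0599 without knockout replicate 1 and 0.104 without knockout replicate 2. Of the 28 lists, 6 passed camera with the preset correlation, 0 with an estimated correlation, and 7 passed fry. These were the interferon gamma response (fry adjusted p = 0.00754), CD4 and regulatory T cell markers (0.00084), apoptosis (0.00162), homing receptors (0.0276) and 3 that single genes carried or could have carried. The inflammasome list (6.77e-05) holds Pycard itself, and 4 of its 11 members were above 0, with a median of -0.01. Cell cycle (0.00084) holds Plk1, and the stromal and endothelial list (0.0326) had 1 measured gene, Pecam1, at 0.22 ± 0.0803, not called over all genes and named after its value was seen.

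**Figure D3:**
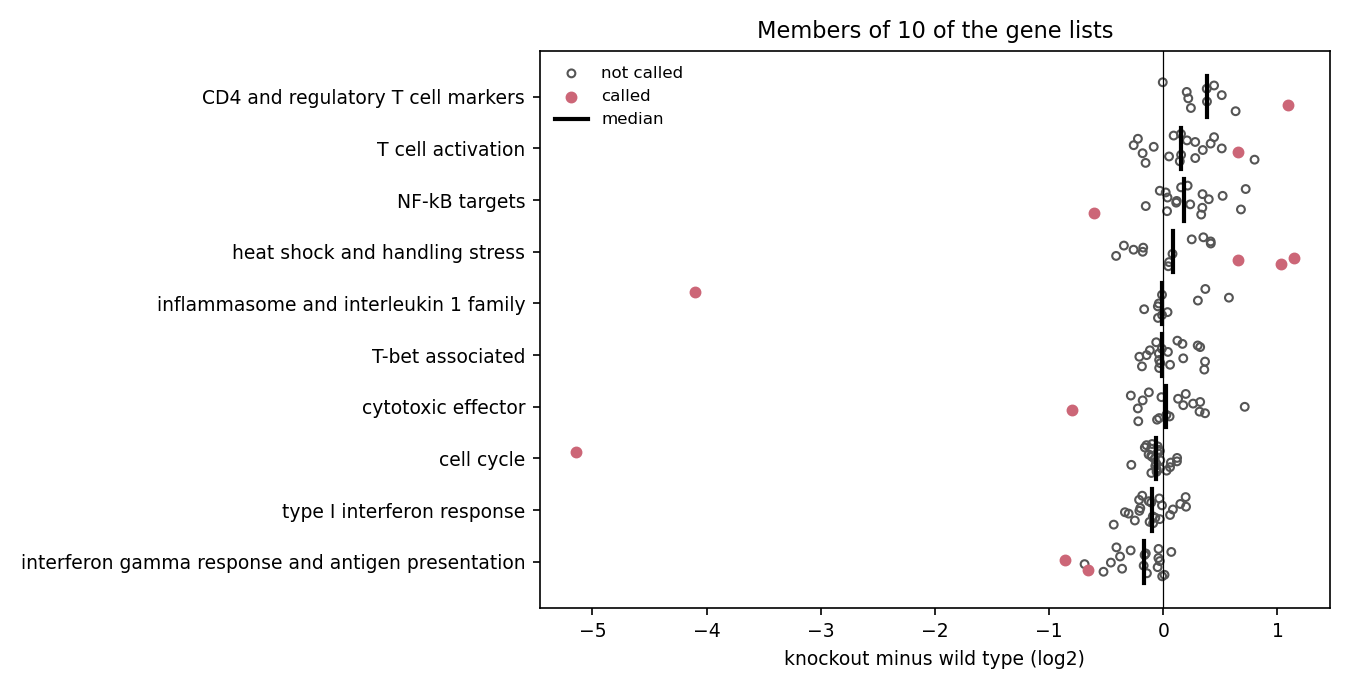
Knockout minus wild type differences (log2) of the measured members of 10 of the gene lists, 1 point per gene; filled red points passed limma's adjusted p over all genes, open points did not, and black bars are list medians. Medians run from -0.17 for the interferon gamma response to 0.38 for CD4 and regulatory T cell markers, while Plk1 and Pycard stand far from the rest of their lists.

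No other list passed camera. Glycolysis had 12 of 16 members below 0 (adjusted p = 0.0592), although its 1 called gene, Pgk1, was higher by 1.17 ± 0.168 at a probe that 1 wild type and 4 knockout arrays detected. Apoptosis genes were at an adjusted p of 0.0592 and myeloid markers at 0.106, both toward higher values. Leaving out 1 array moved the adjusted p of myeloid markers between 0.000947 (without knockout replicate 3) and 0.342 (without knockout replicate 1). It moved that of glycolysis between 0.00146 (without wild type replicate 4) and 0.28 (without wild type replicate 1), and that of heat shock and handling stress between 0.0373 (without knockout replicate 1) and 0.373 (without knockout replicate 4). Adjusted p-values were 0.157 for naive and memory genes, 0.603 for inhibitory receptors, 0.834 for T cell receptor signalling, 0.173 for cytokines, 0.262 for homing receptors and 0.585 for migration and Rac cytoskeleton. They were 0.312 for oxidative phosphorylation, whose member Sdhb was called only at a dimmer probe, 0.603 for ribosomal proteins, 0.86 for lysosome and granule genes and 0.774 for the unfolded protein response. Markers of B cells gave 0.603 with 8 measured genes, NK and innate-like T cells 0.774 with 4, and erythroid cells and platelets 0.251 with 3. Stromal and endothelial markers, at 0.173, had 1 measured gene of 15, so these last 3 lists say little about their cell types. Median, mean and test did not share a sign for inhibitory receptors (median -0.01, mean 0.10, toward higher), the unfolded protein response (median -0.04, mean 0.0044, toward lower) and T cell receptor signalling (median -0.01, mean -0.0048, toward higher). The 2 measured sex-linked genes gave 0.774, with Xist at 0.04 ± 0.142 and Uty at -0.18 ± 0.17. Adjusted over the list alone, 2 naive and memory genes, 3 homing receptors, 1 apoptosis gene, 1 glycolysis gene, 2 unfolded protein response genes, 1 erythroid gene and Pecam1, the only stromal gene, passed, all higher. Among cytokine genes, 3 passed higher and 1 lower when adjusted over the list alone.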

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

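The rule for an array far from its group was set before the data were examined, while probes without a gene name were looked at after their number was seen. An array stood apart when its gap to the nearest other array divided by its group's range exceeded Dixon's 95% critical value. Of 140 groups of 4 values looked at, 10 met this, where chance gives about 1 in 20, or 7.

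Among genes that passed the test, wild type replicate 3 stood above the other wild type arrays for Foxp3, at 6.26 against 5.67 to 5.75 (ratio 0.858), and for Epas1, at 6.66 against 5.62 to 5.78 (ratio 0.85). Wild type replicate 4 was above its group for Cxcr4, at 8.31 against 7.80 to 7.83 (ratio 0.959), and below it for Irgm2, at 8.54 against 9.04 to 9.12 (ratio 0.85). Knockout replicate 4 was below its group for Slc15a2, at 6.34 against 6.69 to 6.72 (ratio 0.928). Knockout replicate 1 was above its group for Tmem254a, at 9.54 against 9.34 to 9.37 (ratio 0.856). The groups of these 6 genes still did not overlap.

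Among genes not called, wild type replicate 1 was below its group for Tbx21, at 9.66 against 9.86 to 9.87 (ratio 0.915), and above it for Il18, at 6.19 against 5.29 to 5.38 (ratio 0.904). The mean of the type I interferon list was 6.83 on knockout replicate 1 against 7.004 to 7.034 on the others of its group (ratio 0.85). The mean of the handling stress list was 10.12 on wild type replicate 3 against 10.04 to 10.05 (ratio 0.861).

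Signal outside the named genes came from 3 probes without a gene name that passed limma's adjusted p, all lower in the knockout, by log2 differences of -1.34 ± 0.167, -0.69 ± 0.123 and -0.61 ± 0.0948 (SE, n = 4 per group).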

How the results depend on the processing

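The lists without shared or called members, the scaling over detected probes and the fit without genes near Pycard were chosen after seeing the data. The named called genes, Pycard among them, the called lists and the Pycard window kept their direction. The other called genes were not followed. Among named genes not called, Tbx21 (-0.17 to 0.0093), Casp1 (-0.06 to 0.07) and Il18 (-0.13 to 0.16) changed sign when 1 array was left out, and some lists far from the threshold changed direction. Genes higher and lower were 100 and 74 with normexp at an offset of 50 and 116 and 90 with trend and robust variance. They were 112 and 88 both without background correction and in the authors' value table. These hold nearly the same values and are not separate checks. Without the detection filter the counts were 30 and 26, and with the replicate block 26 and 20. The cause was not tested. Leaving out 1 array gave 15 to 38 higher and 15 to 32 lower, from fewer samples. The replicate block shared 36 genes with the fit without it. Same-numbered arrays deviated together at correlations of 0.0139, 0.107, 0.132 and -0.0999, and the own number was the best match for 2 of 4, so the numbers were not taken as pairs.

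With an estimated correlation, adjusted p was 0.22 for interferon gamma response, 0.0597 for CD4 and regulatory T cell markers, 0.367 for T cell activation, NF-kB targets and cell cycle, and 0.622 for type I interferon. fry gave 0.0787 for activation and NF-kB and 0.381 for type I interferon. The type I interferon call was also lost with median scaling (0.139), cyclic loess (0.0522), array weights (0.0591), the replicate block (0.0579), gene means (0.0855) and scaling over detected probes (0.099), and cell cycle without genes near Pycard (0.112). Without 1 array, adjusted p ran from 0.00403 to 0.0993 for activation, 0.00173 to 0.104 for cell cycle, 0.00099 to 0.304 for type I interferon and 0.00509 to 0.0571 for NF-kB, while interferon gamma (1.05e-07 to 4.68e-05) and CD4 markers (3.72e-06 to 0.000234) kept their calls. The interferon gamma list without Gbp3 and Irgm2 was at 9.3e-05.

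The Pycard window kept an odds ratio of 2.88 to 8.55 over windows of 10 and 50 Mb, 2 other detection filters and the authors' values. Calls of Plk1, Rgs10, Apobr, Foxp3, Klf4, Rab4a, Msc, Entpd4 and Tmem254a held in 19 of 19 alternatives that tested single probes. These 19 include both the fit without background correction and the authors' values, which are nearly the same. The call of Fos held in 9 of 19, and those of Fosb, Epas1 and Tsc22d3 in 10. The fit on the mean of a gene's probes was not in this count and kept 27 of 29 named calls, Pycard aside. The replicate block and the fit without the detection filter each kept 21 of 29. Il7r passed with normexp at an offset of 50 (adjusted p = 0.0368), without background correction (0.0463) and in the authors' values (0.0464). Of the other lists' results under alternatives, 421 kept their side of the threshold and 28 crossed to it. A block for the slide was not run, as no slide is given in the sources used here. Dim probes lie near background, where fold sizes depend most on the background model.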

Other observations

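Among the tests of explanations, some were chosen only after their own result was seen. These were the tests of higher genes near Pycard, of second probes near Pycard, of loss of ASC as the cause of the cluster and of Ifng. The detection of Cd4 in place of its fold and the splits compared over all lists were also such tests. The division of the lower genes into Itgad and Apobr and the rest was also made after their values were seen. The list without members shared with T cell activation was chosen after seeing the data, with its prediction written before its own result.

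The following called genes were not reached by the naming rule and were chosen here after their values were seen. Cd70 rose by 0.98 ± 0.149, Tnfsf14, or LIGHT, by 0.73 ± 0.14 and the death receptor gene Tnfrsf25 by 0.67 ± 0.124, while Tnfrsf13c fell by 0.60 ± 0.0997, on the log2 scale (SE, n = 4 per group, limma adjusted p between 0.0184 and 0.0455). Dusp4, a phosphatase gene of the same family as Dusp1, rose by 0.76 ± 0.14, and Nfil3, a basic leucine zipper factor, by 0.50 ± 0.0827. Outside the fixed lists, 2 further interferon-inducible genes were lower: Ifi47 fell by 0.64 ± 0.122, and Gbp10, undetected on the knockout arrays, was at least 1.42-fold lower (limma adjusted p = 0.0211). Sdhb was called at a dim probe alone, since its brightest probe differed by -0.06. Of the 24 called genes with 2 or more tested probes, 16 had another probe with the same direction at an unadjusted p under 0.05, and 0 had one in the opposite direction.

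Called genes clustered around Pycard, with an odds ratio of 4.72, as strain DNA kept around a targeted gene would give. If losing ASC protein alone spread calls evenly, which was not tested, the lower end of the interval, 2.05, would go against it. This would hold for the genes as a set, though not for any single gene. It rests on the same odds ratio that showed the cluster, so it is no separate test. A base difference under a probe would lower signal in the knockout where the probe matches the wild type sequence. Probe sequences were not examined, so the 3 higher genes argue against it only on that condition. There were 3 lower genes with 2 or more tested probes. Of these, 2, Itgad and Apobr, had a second probe lower at an unadjusted limma p under 0.05. The second Kdm8 probe was also lower, at -0.24, but missed this cut. The second Apobr probe, at -0.83, was dim, and its groups overlapped. It was detected on 3 of 4 wild type and 1 of 4 knockout arrays, so it is weak evidence for Apobr. Itgad also had a dim probe at 0.11, and for Plk1, Rgs10, Wdr11 and Kdm8, of which 1 had a second probe, a base difference and altered expression cannot be told apart. So the large Plk1 and Gdpd3 differences may reflect the DNA around the target, which the design does not separate from loss of ASC.

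The higher CD4 and regulatory T cell markers may reflect CD4+ T cells in the CD8+ samples or Foxp3 expression within CD8+ cells. The comparison set beforehand had Cd4 at 0.04, with an upper bound of 0.30 below Foxp3's lower bound of 0.78, and would have spoken against mixed cells, but the only Cd4 probe was detected on 1 of 4 knockout arrays and 0 of 4 wild type arrays, so it decided nothing and both stay open. Without the members shared with T cell activation the list stayed past camera at the preset correlation (adjusted p = 0.000217), so the shared members alone did not carry that call. Only shared members were removed, so T cell activation is not excluded as the cause. Of the 35 splits of the arrays, 1, the real one, gave this list a camera p this small, at 6.07 on the -log10 scale against 3.89 for the highest other. The list was weighed for its small p among 28, however, and in 5 of the 35 splits, the real one included, some list had a p as small (highest other 10.67), so chance cannot be excluded, and with an estimated correlation the adjusted p was 0.0597.

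The quantile step is argued against as the cause of the lower interferon gamma response genes. Median scaling and cyclic loess in its place gave camera adjusted p-values of at most 2.29e-06 at the preset correlation. An offset shared by all probes of an array shifts list and other genes alike, so camera could not test such an offset. The authors' values, also planned for this, share the quantile step and could not test that step. Less Ifng transcript stays open. Both Ifng probes were higher in the knockout, at 0.17 and 0.15, and stayed above 0 in every fit without 1 array. Their lower bounds, -0.11 and -0.16, lay above the list's median of -0.17. For the brighter probe, however, this position of the lower bound held in only 5 of 8 fits without 1 array. Handling stress stays open: across the 8 arrays, deviations from group means of the stress and interferon scores had a Pearson r of 0.332 (exact permutation p = 0.182) and Spearman's rho of 0.214 (p = 0.559), and r was 0.363 without the 2 arrays farthest out, so the test showed neither the predicted negative relation nor its absence. Of 35 splits 1, the real one, gave this list such a camera p, at 7.17 on the -log10 scale against 6.23, but in 3 splits, the real one included, some list had a p as small (highest other 10.67), so chance cannot be excluded, and with an estimated correlation the adjusted p was 0.22. A direct effect of ASC on this response was not tested.

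The 88 called genes exceeded every other split of the 8 arrays, the highest of which called 1. So 1 of 35 splits, the real one, gave as many, which is the smallest share that 35 splits can give. The splits do not tell loss of ASC from any other difference between the 2 sets of samples. For the lists the outcome was different: 5 of the 35 splits, the real one included, passed as many lists as the 6 of the real split, and the highest other passed 10, so chance cannot be excluded for their number. Outside the Pycard window, 10 of 78 called genes lay within 2 Mb of another, against 17.2 on average in 100000 random sets (one-sided permutation p = 0.952). So the called genes gave no sign of clustering at this distance. A piece of chromosome with a single called gene would not show in this test, so other pieces that differ are not excluded.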
